A study of Mus musculus with 9 samples.

How the data were processed

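RNA from the hearts of FVB mice aged 14 days was measured on Illumina Mouse-6 v1.1 bead arrays, on which each probe is read on several beads. There were 9 arrays in 3 groups of 3: control, N-line (a transgene of a normal membrane transport protein) and K-line (a transgene of a mutant of that protein that stays active). Per the labels, RNA was purified with a Qiagen RNeasy column, amplified and biotin-labelled with the Illumina TotalPrep kit, and every animal was male. The labels number the arrays within a group but do not state that each came from its own animal, so the p-values measure the spread between these samples, which may be partly technical. No pair of arrays shared more than 327 of the 46657 raw values, so all 9 were kept as separate samples.

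Per the file headers, the authors exported the mean bead intensity of each probe from BeadStudio 2.3.47 with no normalization, with no background subtraction recorded. The deposited detection score is a fraction from 0 to 1 that is higher for brighter probes, so 1 minus the score was used as the detection p-value. The same deposited tables give the number of beads per probe and the spread between beads, which served only to describe the arrays. The authors' value table holds 46643 probes as intensity on a linear scale after background subtraction, as the values show, since between 34.4% and 35.7% of them are negative in each column. How the authors normalized that table is not given in the sources used here. Its 3 K-line columns have medians of 9.28, 9.28 and 9.29 and an upper quartile near 92.9, while the control columns have medians of 7.57, 7.55 and 7.56, the N-line columns 7.57, 7.55 and 7.56, and all 6 an upper quartile near 73.6, so the slides appear to have been normalized separately. It was used only as an alternative. No date, scan setting or image was used.

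Raw intensities were corrected for background with the normexp method of limma 3.58.1 in R 4.3.3, with the noise estimated from the detection p-values. An offset of 16 was added, all 9 arrays were quantile normalized together on the linear scale, and log2 was then taken. Probes with a detection p-value under 0.05 on at least 3 arrays were tested, which left 19692 probes. A single limma model with 3 group means was fitted with lmFit and eBayes, so that the groups share an estimate of the spread, and p-values were adjusted over the probes by the Benjamini-Hochberg method at a threshold of 0.05. Differences are log2 differences of group means, with the standard error (SE) of the fit, and levels are mean ± standard deviation (SD) over 3 arrays. Where a probe was below background on every array of a group, the difference is also given as a bound, written "at least N-fold". It is the brighter group's mean over the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among detected probes. The number of arrays limits the precision of every value.

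The arrays carry their own probe codes and no gene symbols. Codes of 1 class hold a number after 1 or 2 leading zeros, and 9796 of their 11857 numbers (82.6%) are mouse NCBI gene numbers in the RefSeq gene table of assembly GRCm38.p6. After shifting the numbers by 1 to 20, at most 46.0% were. In the class without a leading zero 11.3% matched, against 11.1% after shifting, and that class was left unnamed. The reading of this number as a gene number was inferred from these matches. In the named class the 9 cardiac contraction probes had a median brightness percentile of 94.8, and the 5 lung and liver probes 52.9. Over 541 genes with several tested probes, the K-line differences of a gene's first pair of probes correlated at 0.644 (across genes, which are not independent), against at most 0.163 in 1000 shuffles. A further 9 probes were named through a RefSeq accession, which gave 9805 named probes for 8106 genes. Among the tested probes 5215 (26.5%) were named, for 4619 genes, so gene lists are measured only in part. Clone names were not used, because synonyms matched the wrong genes, and since no build of the array is given, no coordinates are printed. The level of the transgene is not reported here.

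The comparisons were K-line with control, N-line with control and K-line with N-line. For each, 33 gene lists fixed before the data were examined were described by their members, and those with at least 5 measured genes (25 lists) were tested with limma's camera at a preset correlation of 0.01, with the brightest probe of each gene. Camera asks whether a list lies higher or lower than the other measured genes. It was repeated with a correlation estimated from the data, and with fry, which asks whether a list's own genes move on balance in 1 direction. The genes named are, per comparison, the 8 largest rises and the 8 largest falls among adjusted p-values under 0.05, with the probe detected on all 3 arrays of the higher group, no overlap of the groups and a symbol that is not a predicted name, with 1 probe per gene. In addition up to 4 members of each list with the smallest adjusted p and, for lists of other cell types, the members of highest signal are named. The list called osteopontin and extracellular matrix was built with osteopontin in mind, from what is known of this study, so it is not independent evidence of its direction.

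Alternatives fixed before the data were examined were median scaling, no background correction, the authors' value table with a floor of 16, no filter or a stricter filter (detection p under 0.01 on all 3 arrays of a group), only the compared groups in the model, array weights, a trended and robust spread, a minimum change of 1.5-fold, 1 probe per gene, the replicate number as a block, the slide that holds both N-line and control normalized alone, and leaving out each array in turn. Leaving out probes named on chromosome X or Y was added after seeing the data. The K-line arrays are on a slide of their own, so a slide block could not be fitted for them. They were also exported in a raw table of their own, so a difference between runs could not be told apart from K-line either. The correlation of K-line and N-line responses was set beside 100 simulations of unchanged groups against shared controls. The model was tested on simulated data for K-line against control with 19692 probes, 200 of them changed. It recovered 2% of changes of 0.5 on the log2 scale, 89.5% of changes of 1 and 99% of changes of 2, with 20% (of 5 calls), 2.72% and 7.48% of the calls false, and made 0 calls where nothing was changed. A list shifted by 0.5 in the simulation was called and 0 others were. The simulated noise was independent between genes, and fewer probes changed than the 4795 called in K-line. The shares recovered may therefore not hold for the real data, and correlation within a list was not simulated.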

Results

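The 9 arrays were of similar quality. Between 17937 and 19021 of 46657 probes were detected per array (38.4% to 40.8%), with a median of 35 to 38 beads per probe and a median bead-to-bead coefficient of variation from 4.10% to 4.54% among detected probes. After normalization the arrays of 1 group correlated at 0.988 to 0.995 across probes, control with N-line arrays at 0.989 to 0.993, and K-line with the other arrays at 0.969 to 0.981. The first principal component held 55.6% of the variance and separated K-line from the other 6 arrays, and the second held 11.3%.

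**Figure D1:**
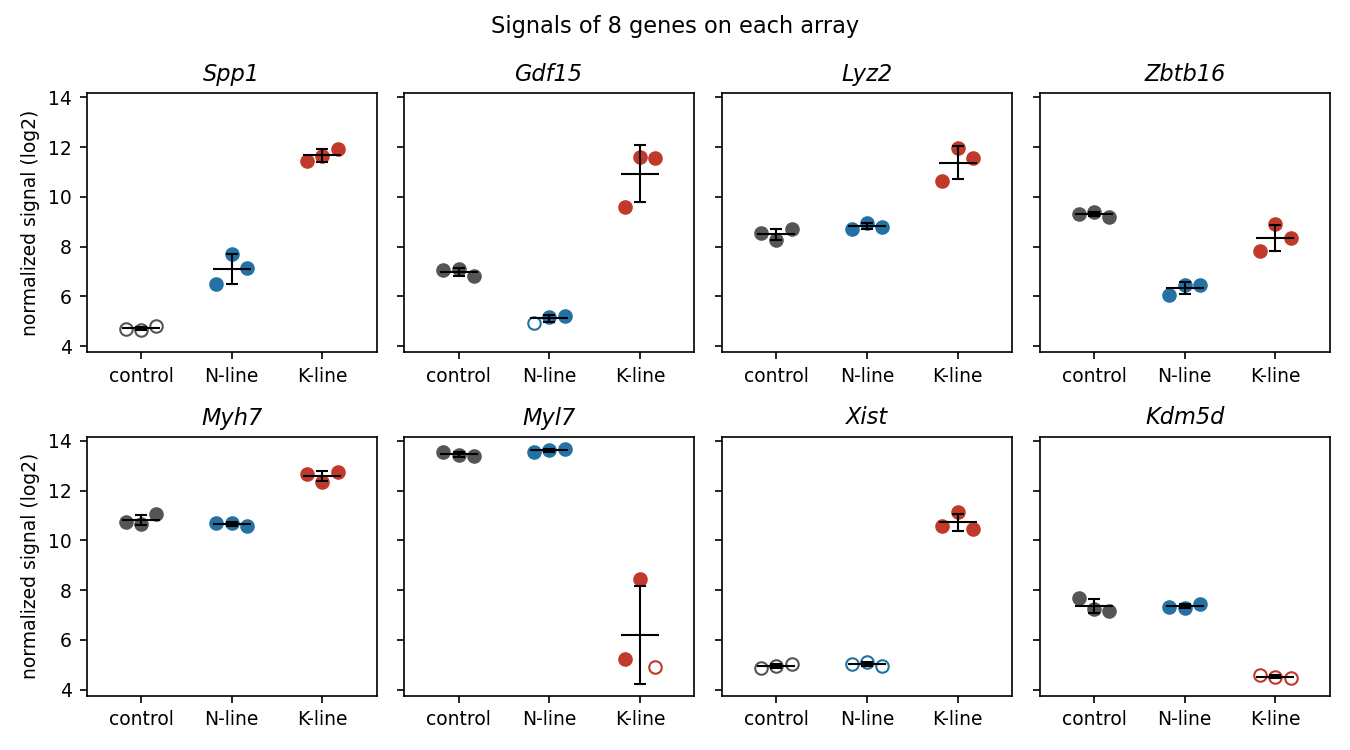
Normalized signal (log2, y axis) of 8 genes on each array by group (x axis), 3 arrays per group. Filled points are detected probes, open points are below background, and the bar gives the mean ± SD. Spp1 is below background on all 3 control arrays and highest on the K-line arrays, and Zbtb16 is lowest on the N-line arrays.

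The K-line comparison asks which genes differ in hearts that carry the transgene of the mutant that stays active. Spp1, which encodes the secreted matrix protein osteopontin, rose by 6.96 on the log2 scale (SE 0.24, n = 3 per group), at least 91.7-fold, from below background on all 3 control arrays to 11.67 ± 0.25 (SD), with an adjusted p of 3.50e-08. Gdf15, a stress-induced cytokine of the TGF-beta family, rose by 3.94 (SE 0.42, adjusted p 1.05e-04), and the membrane glycoprotein Gpnmb, detected on 1 of 3 control arrays, by 4.28 (SE 0.12, adjusted p 7.87e-09). Myh7, the slow myosin heavy chain that is raised again in stressed mouse ventricle, rose by 1.77 (SE 0.13, adjusted p 1.15e-05) to 12.58 ± 0.21. Eln, which encodes elastin, fell by 2.51 (SE 0.16, adjusted p 4.24e-06). The other largest rises were Xist (5.78, at least 47.8-fold), Alk (4.02, at least 11.4-fold), Cd72 (3.26, at least 7.29-fold) and the near-identical pair Bcl2a1d and Bcl2a1a (3.37 and 3.32), whose probes may not tell these paralogs apart. Myl7, the atrial myosin light chain, showed the largest fall (-7.28, SE 0.69, adjusted p 5.18e-05), with signals of 5.22 and 8.44 on the 2 K-line arrays that detected it, against 13.38 to 13.57 in the controls. The falls of Cacna2d2 (-2.19), Syn2 (-2.17), Upk3b (-1.77) and Ppl (-1.74, detected on 1 of 3 K-line arrays) came next, besides the Y-linked genes Kdm5d (-2.84, at least 4.76-fold) and Ddx3y (-2.05, at least 2.63-fold), which were below background on all 3 K-line arrays.

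Markers of macrophages and leukocytes rose together in K-line. Of 11 measured, 10 rose and 0 fell, with a median of 1.53, and the bright lysozyme Lyz2 went from 8.49 ± 0.22 to 11.38 ± 0.68. Further rises were the chemokine Ccl2 (1.96) and the macrophage antigen Cd68 (1.85), each detected on 2 of 3 control arrays, the complement gene C1qb (1.53) and the Fc receptor Fcgr3 (1.49). Camera placed the list above the other genes with an adjusted p of 8.51e-09, and with an estimated correlation the adjusted p was 0.236. Of the 8 hypertrophic ligands and receptors, 5 rose and 0 fell, among them Gdf15, Igf1 (0.60), the beta-adrenergic receptor Adrb1 (0.58, detected on 2 of 3 control arrays) and Igf1r (0.44), with an adjusted p of 0.0128 (0.236 with an estimated correlation). In the oxidative stress and glutathione list 4 of 10 rose and 1 fell (5 and 1 adjusted over the list alone), with the sulfiredoxin Srxn1 at 1.44, Prdx6 at 0.61, Sod1 at 0.41 and Gstp1 at 0.33. Its adjusted p was 0.0340 (0.534 with an estimated correlation), and the call ended with median scaling, with the authors' value table, with the mean of all probes of a gene, or without control 3, K-line 5 or K-line 6. Of 37 ribosomal proteins 7 rose, such as Rpl6 (0.51), Rpl4 (0.48), Rps23 (0.46) and Rps4x (0.43), and 36 were higher, with a median of 0.14 and an adjusted p of 0.00236 (0.438 with an estimated correlation). With the authors' value table, in which the median of all probes was 0.23 higher in K-line, the ribosomal median lay 0.02 below that of all probes (-0.02), although the list was still called higher there. With median scaling the list was no longer called. The 28S ribosomal RNA probe, looked at after the list was seen, rose by 0.58 (adjusted p 0.0112) but was dim (5.58 in control). The bright 18S ribosomal RNA probes were at 0, 0.05 and -0.06 and did not pass the test. Relative to all probes in the authors' value table, the medians were 1.81 for macrophage and leukocyte markers and 0.66 for ligands and receptors. They were 0.23 for oxidative stress and -0.32 for oxidative phosphorylation.

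Among genes of energy metabolism camera called 1 list, oxidative phosphorylation and mitochondrial biogenesis. Fry called it lower as well (adjusted p 0.00253), with the fatty acid (0.0392) and tricarboxylic acid cycle (0.0461) lists. The glycolysis list was not called by fry (0.0775). Of 19 oxidative phosphorylation and mitochondrial biogenesis genes 8 fell and 0 rose, with Ndufa10 of complex I at -0.69, the ATP synthase gene Atp5c1 at -0.47, cytochrome c1 (Cyc1) at -0.47 and Sdhb at -0.35 (median -0.13). The adjusted p was 0.00921, and 0.438 with an estimated correlation. Of 12 probes for mitochondrially encoded respiratory chain genes, looked at after the list was seen, 0 passed the test, with COXI at 0.34 (adjusted p 0.0782) and ND3 at -0.26, but most are among the brightest probes, where a change may not show. In the tricarboxylic acid cycle 1 of 9 fell (Pdhb, -0.71; adjusted p of the list 0.128, and 0.0371 with the authors' value table), and in fatty acid uptake and oxidation 2 of 10 fell (1 adjusted over the list alone), Acsl1 at -0.70 and Hadhb at -0.26 (0.138). In glycolysis and glucose transport 4 of 16 rose, Hk1 (0.57), Gpi1 (0.39), Aldoa (0.34) and Ldha (0.27), with a list adjusted p of 0.753. Adjusted over the list alone, the counts of every list in this comparison equal those given unless stated.

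**Figure D2:**
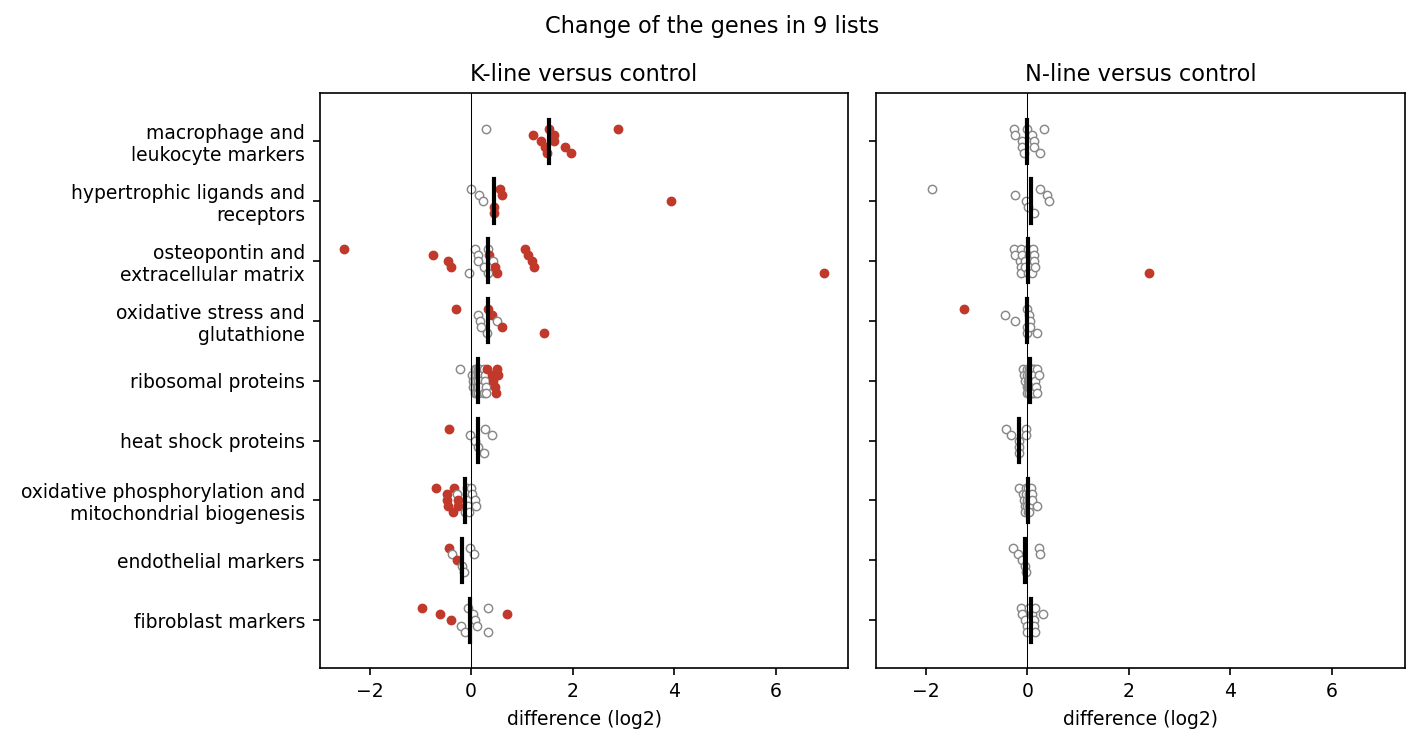
Difference from control (log2, x axis) of the measured genes in 9 lists (y axis), for K-line on the left and N-line on the right. Each point is a gene, filled where its adjusted p was under 0.05, and the bar is the median of the list. In K-line 10 of 11 macrophage and leukocyte markers rose, and in N-line 0 of 11 did.

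In the further lists tied to cardiac growth and function, single genes moved in both directions in K-line, and camera called none of these lists. With fry, the hypertrophy (adjusted p 0.0134), potassium channel (0.0175) and contraction (0.0314) lists were called higher. So were the matrix (0.00382) and calcineurin (0.00382) lists, while the transport list was not called (0.316). Of 5 hypertrophy and fetal gene markers Myh7 and the transcription factor Gata4 (0.46) rose and the smooth muscle actin Acta2 fell (-0.78), with a list adjusted p of 0.391. Of 20 osteopontin and extracellular matrix genes 8 rose and 4 fell (9 and 4 adjusted over the list alone), with Thbs1 at 1.25 (at least 2.03-fold) and Ccn1 at 1.12 beside Spp1 and Eln (0.0923). The calcineurin, CaMKII, GSK3 and hypertrophic transcription factor list held 3 rises and 1 fall in 13 (5 and 1 adjusted over the list alone; 0.128), with the calcineurin subunit Ppp3ca at 0.49, Mef2a at 0.39 and Nfatc1 at -0.54. Without K-line 5, Mef2a was at 0.25 and not called. Of 7 contraction and calcium handling genes Cacna1c (0.34) and Mybpc3 (0.34) rose and the ryanodine receptor Ryr2 fell (-0.57), with a list adjusted p of 0.667. Of 5 potassium channel and excitability genes Kcne1 (1.68) and Kcna5 (1.12) rose and Gja5 (-0.73) and Kcnd2 (-0.71) fell (0.753). Of 11 sodium, proton and bicarbonate transport genes 1 rose and 2 fell, the anion exchangers Slc4a2 (-0.32) and Slc4a3 (-0.31) (0.549). The medians of the potassium channel and transport lists were -0.06 and -0.13, and with the authors' value table they turned to 0.09 and 2.67e-04. Both stayed below the median of all probes in that table, which was 0.23.

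Of 6 immediate early genes 4 rose and 1 fell (4 and 2 adjusted over the list alone), with Egr2 at 2.41, Junb at 1.39, Fosl2 at 0.51 and Egr3 at -0.64, and a list adjusted p of 0.128, or 0.0375 with the stricter filter. In the autophagy, ubiquitin ligase and atrophy list Sqstm1 (1.11) and Ctsb (0.40) rose among 8 (0.549), and in the apoptosis and p53 list Bcl2l1 (0.47) and Bcl2 (0.40), which oppose cell death, rose among 5 (0.291). Of 14 cell cycle genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; 0.998), with Pcna at 0.49, Mki67 at 0.40 and Cenpa at -0.72. Without K-line 6, Mki67 was at 0.27 and not called. Hsf1 fell (-0.44) among 7 heat shock genes (0.630), Igtp rose (0.98) among 6 interferon genes (0.549), and the imprinted gene Peg3 fell (-0.59) among 5 (2 adjusted over the list alone; 0.667). The 4 endoplasmic reticulum stress genes had 0 calls, with Hspa5 at 0.46 (adjusted p 0.0761), and the 2 clock genes had 0 calls (1 rise adjusted over the list alone, Nr1d2 at 0.54). The median, mean and test differed in sign for potassium channels (mean 0.26, camera up) and imprinted genes (median 0.02, mean -0.13, camera down). Fry called the immediate early (adjusted p 0.00117), autophagy (0.0175) and apoptosis (0.0345) lists higher. It did not call the cell cycle (0.982), heat shock (0.316), interferon (0.0785) or imprinted (0.159) lists.

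Of 7 endothelial markers 2 fell (3 adjusted over the list alone), Robo4 at -0.43 and the bright Cav1 at -0.29 (list adjusted p 0.128), with a median of -0.17. With the authors' value table the median became 0.0049, while that of all probes was 0.23. The list was then called lower than the other genes by camera (adjusted p 0.0437). Fry called the endothelial list lower (adjusted p 0.0254), but not the fibroblast (0.711), red blood cell (0.0601) or adipocyte (0.711) lists. Of 12 fibroblast markers Pcolce rose (0.71) and Igfbp6 (-0.97), Fbln1 (-0.62) and Islr (-0.41) fell (2 and 3 adjusted over the list alone; 0.753), while the brightest, Dcn and Mgp, were at 0.03 and 0.12; the median of -0.02 became 0.10 with the authors' value table. Among red blood cell markers Dmtn (-1.26) and Ank1 (-0.99) fell in 6 (0.128), and the globin Hba-a1 was at -0.03. The list was called lower with median scaling (0.0412), with the authors' value table (0.0351) and without K-line 3 (0.00591). The 5 adipocyte markers had 0 calls (0.753) and a median of -0.41, with Acly at 0.02 and Car3 at -2.86 (SE 1.46, adjusted p 0.179). Car3 was uneven within groups, from 8.36 to 11.56 in control and from 4.68, below background, to 11.48 in K-line. Lists with too few genes for a test held Acta2 (-0.78) as the fall among 2 smooth muscle markers (2 adjusted over the list alone), Gap43 (-0.63) among 2 nerve markers, and Lyz1 (1.64, detected on 1 of 3 control arrays) as a rise among 2 lung and liver markers, a gene that is also on the macrophage list. The 4 T cell markers and the skeletal muscle marker Casq1 (-0.26) had 0 calls, with Satb1 at 0.17, and the T cell median of -0.02 became 0.28 with the authors' value table. Of 4 atrial and conduction markers Myl7, Cntn2 (-0.98) and Gja5 fell (4 adjusted over the list alone).

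In total 4795 of 19692 probes changed in K-line against control by limma, 2359 up and 2436 down, of which 2032 changed by at least 1.5-fold, and 7428 had an unadjusted p under 0.05. For 40.6% of the probes the groups did not overlap, against 10% by chance. Named genes made up 689 rises and 588 falls. The calls of Adrb1, Aldoa, Bcl2, Bcl2l1, Cacna1c, Cav1, Gata4, Gstp1, Hadhb, Hk1, Igf1r, Islr, Kcnd2, Ldha, Lyz1, Mef2a, Mki67, Mybpc3, Pcna, Peg3, Rps23, Slc4a2 and Slc4a3 ended with at least 1 of the arrays left out, with the direction kept. With median scaling or the authors' value table, the calls of Aldoa, Cav1, Egr3, Hadhb, Islr, Kcnd2, Ldha, Nfatc1, Peg3, Rps23, Ryr2, Sdhb, Slc4a2 and Slc4a3 ended, with the direction kept. The share of changed probes that were higher was 49.2%, and it was 70.5% with median scaling (3030 up, 1267 down) and 84.7% with the authors' value table (5822 up, 1054 down). Some measured facts go with every K-line value. The K-line arrays are on their own slide, the labels call the animals male while Xist was detected on 3 of 3 K-line arrays and on 0 of the other 6, with Kdm5d, Ddx3y and Eif2s3y detected on 0 of 3, and the atrial gene Myl7 was low. The Y-linked genes Rbmy (-0.38) and Zfy2 (-0.17) did not pass the test and were detected on 3 and 2 of the K-line arrays. Slide and K-line cannot be told apart, and without probes named on chromosome X or Y, a choice made after seeing the data, 4763 probes changed. That step kept 19520 of the 19692 probes, and most tested probes have no name. The count therefore cannot show how much of the K-line difference goes with sex.

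The N-line comparison asks which genes differ in hearts that carry the normal form as a transgene. Zbtb16, a zinc finger transcription factor, showed the largest fall (-2.99, SE 0.22, n = 3 per group, adjusted p 1.28e-04), from 9.30 ± 0.09 to 6.32 ± 0.24 (SD). Spp1 rose by 2.40 (SE 0.24, adjusted p 0.00161), at least 3.89-fold, from below background to 7.11 ± 0.60. Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 1.54 (SE 0.22, adjusted p 0.0104), and its second probe also fell by 1.54 (SE 0.12, adjusted p 1.61e-04). Mt1, the metal-binding metallothionein, fell by 1.25 (SE 0.15, adjusted p 0.00459), and the nuclear receptor Nr4a3 by 1.11 (SE 0.13, at least 1.82-fold, adjusted p 0.00361).

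Further rises in N-line were Erdr1 (1.18), Myo5c (1.16), Klra10 (1.03, at least 1.68-fold), Nav3 (0.89), Bcl2a1a (0.83), Bcl2a1d (0.81) and the conduction system connexin Gja5 (0.78). The other tested probe of Erdr1 was not called as a rise. Further falls were Dct (-1.09, at least 1.87-fold), Rhobtb1 (-0.94), Rfx2 (-0.91) and Ppfia1 (-0.91). Gdf15 lay 1.87 lower (-1.87, SE 0.42) and missed the threshold with an adjusted p of 0.0704. In the gene lists the calls were few. Spp1 rose among 20 osteopontin and extracellular matrix genes (1 of 20), Gja5 among the potassium channel and atrial lists, Pfkfb2 fell among 16 glycolysis genes (-0.76), and Mt1 and Cdkn1a fell in the oxidative stress and apoptosis lists. Of 11 macrophage and leukocyte markers 0 rose and 0 fell, with Lyz2 at 0.33 and a median of -0.02 (adjusted p 0.815), and Myh7 was at -0.15 among 5 hypertrophy and fetal gene markers with 0 calls (1 fall adjusted over the list alone; 0.406).

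Of 7 heat shock genes 0 passed on their own (1 fall adjusted over the list alone), and 0 were higher than in control, with Hsp90aa1 at -0.42 and Hspb1 at -0.33 and a median of -0.16. Camera gave the list an adjusted p of 0.0489 (0.711 with an estimated correlation). Of 37 ribosomal proteins 0 passed on their own and 30 were higher, with Rpl6 at 0.23, a median of 0.05 and an adjusted p of 0.0413 (0.711 with an estimated correlation), and median scaling turned the median to -0.04 and ended the call. With control 2, control 3, N-line 3 or N-line 4 left out, 0 lists were called, and the heat shock call also ended without N-line 2, with the replicate block and with the mean of all probes of a gene. The other 23 lists with a test were not called, but the hypertrophy and fetal gene list was called lower with only the compared groups in the model (adjusted p 0.0377) and with their slide normalized alone (0.0376). Adjusted over the list alone, there was 1 fall among calcineurin and transcription factor genes, 1 fall among red blood cell markers, 1 rise among T cell markers, 2 rises and 1 fall among ligands and receptors, and 1 rise and 1 fall each among immediate early genes and nerve markers, where 0 passed over all probes. The median, mean and test differed in sign for ligands and receptors (0.07, -0.12, camera up), calcineurin and transcription factor genes (-0.02, -0.01, up), tricarboxylic acid cycle genes (0.0049, -2.74e-04, up), immediate early genes (-0.0016, 0.01, up), macrophage markers (-0.02, 0.01, up) and red blood cell markers (0.04, -0.06, down).

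In total 183 probes changed in N-line against control by limma, 68 up and 115 down, of which 146 by at least 1.5-fold, with 20 named genes higher and 33 lower. At an unadjusted p under 0.05 there were 2320, and 19.7% of probes had groups without overlap, against 10% by chance. The count moved with single arrays: it was 48, 63 and 70 without control 1, 2 or 3, and 52, 77 and 25 without N-line 2, 3 or 4. With the replicate number as a block, where only the arrays numbered 2 and 3 inform the difference, it was 16. With the slide of both groups normalized alone it was 354. Of the 18 probes called for genes named in N-line, that of Zbtb16 and the second of Cdkn1a were called in every setting. All 18 kept their direction.

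The comparison of the transgenic lines asks where the active mutant and the normal form differ. Gdf15 was 5.82 higher in K-line (SE 0.42, n = 3 per group, adjusted p 8.34e-06), at 10.93 ± 1.15 (SD) against 5.11 ± 0.16 (detected on 2 of 3 N-line arrays), and Spp1 was 4.56 higher (SE 0.24, adjusted p 1.17e-06), so the Spp1 signal differed between the lines, whose arrays are on different slides. Gpnmb, Alk (4.05, at least 11.9-fold), Cd72 (3.08, at least 7.56-fold), Lyz2 (2.56) and Bcl2a1d (2.55) were higher in K-line too, as was Xist (5.71, at least 49.6-fold). Lower in K-line were Myl7 (-7.44), Kdm5d (-2.84, at least 4.77-fold), Eln (-2.40), Cacna2d2 (-2.37), Ddx3y (-2.26, at least 3.03-fold), Syn2 (-1.97), Upk3b (-1.85) and the water channel Aqp4 (-1.64).

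Of the macrophage and leukocyte markers 10 of 11 were higher in K-line than in N-line, with a median of 1.56, Cd68 at 2.10 (detected on 1 of 3 N-line arrays) and C1qb at 1.60, and an adjusted p of 8.99e-09 (0.245 with an estimated correlation). Of 19 oxidative phosphorylation genes 7 were lower (8 adjusted over the list alone), with Ndufa10 at -0.60 and Cyc1 at -0.47 and an adjusted p of 0.00263 (0.377 with an estimated correlation). Of 10 oxidative stress genes 6 were higher and 1 lower (7 and 1 adjusted over the list alone), with Srxn1 at 1.90 and Mt1 at 1.43, and an adjusted p of 0.0153 (0.469 with an estimated correlation). It was not called with the authors' value table. Of 5 apoptosis and p53 genes Cdkn1a (1.25), Bcl2l1 (0.74) and Bcl2 (0.57) were higher, with an adjusted p of 0.0223 (0.377 with an estimated correlation), and the call ended without K-line 5. Of 5 hypertrophy and fetal gene markers 3 were higher and 1 lower (4 and 1 adjusted over the list alone; 0.121), with Myh7 at 1.93, Enah at 0.90 and Xirp2 at 1.54. Without K-line 5, Xirp2 was at 0.89, still called, and its call ended without N-line 2 or N-line 3 (1.55 and 1.41). Of 7 heat shock genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone; 0.106), with Hsp90aa1 at 0.84, and of 37 ribosomal proteins 4 were higher (1 adjusted over the list alone; 0.106). Adjusted over the list alone, the counts also differed for calcineurin and transcription factor genes (5 higher against 4), potassium channels (2 lower against 1), immediate early genes (1 lower against 0), interferon genes (0 higher against 1) and endothelial markers (0 lower against 1). For potassium channels the median was -0.28, the mean 0.12 and the test down. Fry called the hypertrophy (adjusted p 0.00133), heat shock (0.00559), ribosomal (0.0173), immediate early (0.00133) and calcineurin (0.00427) lists higher in K-line. It called the endothelial list lower (0.0358), and did not call potassium channels (0.633) or interferon genes (0.428).

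In total 4774 probes changed between the lines by limma, 2377 higher and 2397 lower in K-line, with 7323 at an unadjusted p under 0.05 and no overlap for 39.5% against 10% by chance. Without N-line 2 the count was 3044. The higher share was 49.8%, against 76.6% with median scaling (3434 up, 1049 down) and 85.9% with the authors' value table (5879 up, 965 down), where the median of all probes lay 0.12 and 0.23 higher in K-line. Here too the K-line arrays are on their own slide, with the sex-linked and atrial differences given above.

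**Figure D3:**
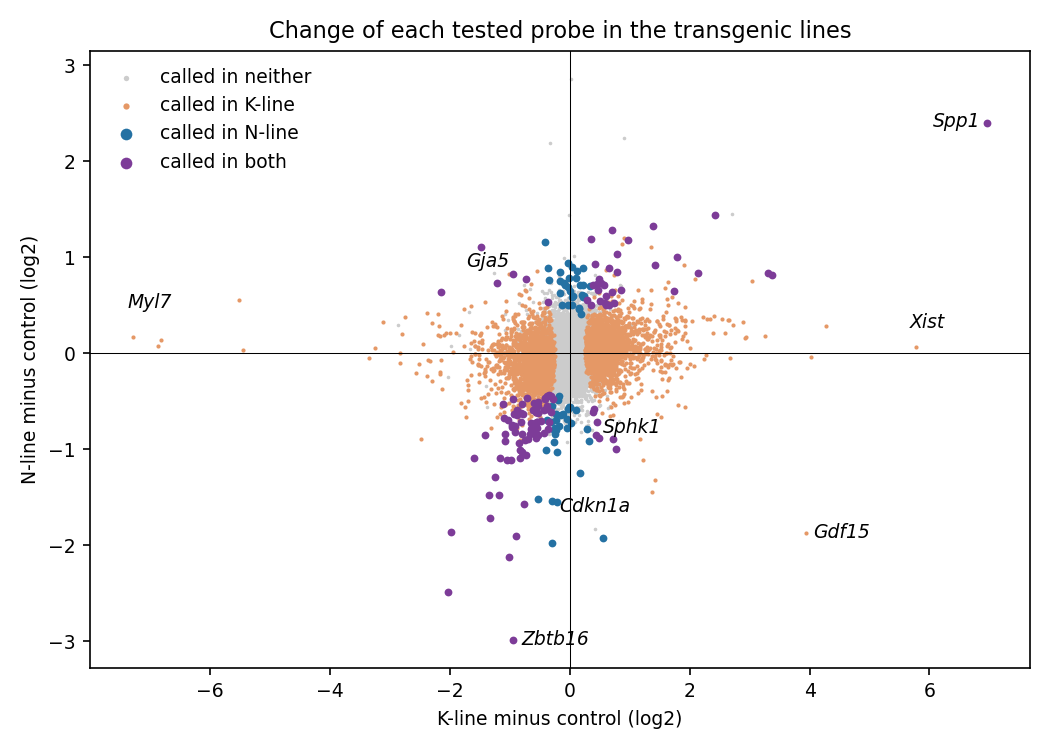
Difference from control (log2) of each of the 19692 tested probes in K-line (x axis) and in N-line (y axis), coloured by where the adjusted p was under 0.05. Spp1 rose in both lines, and Gja5 and Sphk1, the latter named after its values were seen, moved in opposite directions.

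The responses of the lines were then compared with each other. Spp1, below background in control, rose in both lines, by 6.96 in K-line (at least 91.7-fold) and 2.40 in N-line (at least 3.89-fold). Zbtb16 fell in both, by 0.95 and 2.99. Both differences between the lines passed the limma test (adjusted p 1.17e-06 and 1.23e-04). Among probes called in both lines 32 rose in both (8.15 would be shared by independent lists) and 76 fell in both (14.2), while 7 rose in K-line and fell in N-line (13.8) and 6 did the reverse (8.41). Over 4619 genes the log2 differences correlated at 0.280 (Spearman 0.288), across genes, which are not independent replicates. Unchanged groups against shared controls gave 0.495 in simulation, with a covariance of 0.00956 against the observed 0.0259, a difference of 0.0164. The share of genes with the same sign was 60.1%, against 66.7% simulated. The simulation held no changed genes, while the observed differences had an SD of 0.460 in K-line and 0.201 in N-line. Changes in K-line alone lower both the correlation and the same-sign share. Neither can therefore show that the lines are less alike than unchanged groups. The covariance is not lowered in this way. The 3 control arrays are too few for separate sets of at least 2, so part of the excess overlap may come from the shared controls.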

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

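Gja5, the connexin of the atria and the conduction system, was lower than control in K-line (-0.73) and higher in N-line (0.78), a difference between the lines of -1.50 with an adjusted p of 3.05e-05 by limma. Sphk1, a sphingosine kinase named after its values were seen, was higher in K-line (0.44) and lower in N-line (-0.85), a difference of 1.30 with an adjusted p of 1.77e-05. What brought both up is that their differences from control have opposite signs in the lines. Gja5 is also among the atrial markers that were low on the K-line arrays, and slide, sex and K-line cannot be told apart here. Gja5 in N-line lost its call without control 1, control 3, N-line 2, N-line 3 or N-line 4, without a filter, and with the replicate block.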

How the results depend on the processing

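Of the called probes of named genes, 57 of 86 were called in every setting for K-line against control, 2 of 18 for N-line against control and 61 of 88 for K-line against N-line, and all kept their direction. With the replicate block alone, 15 of the 18 N-line probes lost their call. The probe counts of K-line against control moved by over 1.5 times only with at least 1.5-fold change as well (2032) and with 1 probe per gene (1307 of 4619 genes, fewer tested). Between the lines the same settings gave 2023 and 1239, and leaving out an array gave 3044 to 4780 (3327 to 4692 for K-line against control). The N-line count of 183 became 109 with median scaling, 314 with only its groups in the model, 452 with array weights, 308 with a trended and robust spread, 63 with 1 probe per gene, 354 with its slide normalized alone, and 25 (without N-line 4) to 77 (without N-line 3) with an array left out. With the replicate number as a block 16 remained called, 2 up and 14 down. In that fit, arrays whose number is not shared between N-line and control add nothing to their difference. Little is then left to estimate the spread, so a loss of calls follows from the model itself. Only numbers 2 and 3 are shared between N-line and control, with correlations of deviations of 0.224 and 0.109 within and -0.062 and -0.270 across, too few pairs to say that the numbers pair the samples. The cause of the other moves was not tested. None of these probes changed direction, but the medians of several lists changed sign with the scaling, the called N-line ribosomal list among them, and the balance of higher and lower probes moved. Leaving out probes named on chromosome X or Y, chosen after the result was seen, gave 4763, 182 and 4732 probes. Gene lists for K-line against control were 5, but 0 with an estimated correlation and 16 with fry, and 4 to 6 with an array left out. For N-line against control they were 2, but 1 with median scaling, 1 with the replicate block, 0 with an estimated correlation, 0 with fry, 1 with the mean of all probes of a gene, and 0 to 2 with an array left out. Between the lines they were 4, but 8 with no filter, 0 with an estimated correlation, 14 with fry, and 3 to 5 with an array left out. The correlation of the responses went from 0.224 to 0.324 with an array left out. Slide as a block could not be fitted for K-line. Signal over background limits the differences of dim genes.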

Other observations

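Tests of slide differences with random gene sets, of sex or slide behind the macrophage markers, of the share of muscle cells, of swapped samples and of glucocorticoid-induced genes were chosen after the result was seen, as were the genes named in the next sentences. In K-line, further genes rose by limma. Cd74, the invariant chain of class II molecules, rose by 2.29 (SE 0.16, n = 3, adjusted p 5.68e-06), H2-Ab1 by 1.92 (SE 0.23, adjusted p 2.26e-04), the pattern receptor Clec7a by 2.34 (SE 0.15, adjusted p 3.33e-06) and the macrophage elastase Mmp12 by 2.39 (SE 0.33, adjusted p 5.97e-04). Prg4, which encodes lubricin, fell (-1.63, SE 0.23, adjusted p 5.97e-04).

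Xist was high and Kdm5d, Ddx3y and Eif2s3y were low on the K-line arrays, although the labels call the animals male. The mean shift of Xist and 5 Y-linked genes in the directions of sex was 2.02, and 0% of 10000 brightness-matched random sets moved as far. The set was taken up because Xist, Kdm5d and Ddx3y were among the largest changes. The share therefore restates the pattern and does not decide on a slide difference that ignores the gene. A swap of single arrays within the series is argued against by 0 control and N-line arrays with detected Xist. The labels call every animal male, but these signals go against that label, so it cannot decide on an exchange of whole groups. Such an exchange and a swap with an outside sample stay open. Rbmy and Zfy2, also Y-linked, were detected on 3 and 2 of the K-line arrays and did not pass the test (-0.38 and -0.17). Zfy2 was dim in every group, with means of 5.23 in control, 5.07 in K-line and 5.04 in N-line. It was detected on 1 N-line array, so its detection does not separate K-line from N-line. The second Xist probe was also detected on 3 K-line arrays (6.99 to 7.76) and on 0 control and 0 N-line arrays. Hearts from female animals may be the cause, since they would give these Xist signals and no Kdm5d, Ddx3y or Eif2s3y. Of the genes known to escape X inactivation only Kdm6a was tested, at 0.49 (adjusted p 0.00350), and 1 gene is too few to decide.

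Myl7, Cntn2 and Gja5 fell on the K-line arrays, and 0% of 10000 matched random sets had a median as low as the 4 atrial and conduction markers. The list was fixed beforehand, but it was tested here because its falls had been seen. The share therefore restates them and does not decide on a slide difference that ignores the gene. Less atrial tissue in the K-line samples may be the cause: 7 further atrial genes, fixed before their values were looked up, had a median of -0.40, and 0.27% of random sets were as low. Gnao1 (-0.98) and Vsnl1 (-0.67) fell, while 3 of the 7 were higher. A biological effect of the active mutant on atrial genes was not tested and stays open.

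Macrophage and leukocyte markers rose in K-line, and 0% of 10000 matched random sets had a median as high. This test was chosen after the rise was seen and restates it. It shows only that sets of similar brightness did not rise as far. A lower share of heart muscle cells would raise the markers of every other type alike, and the higher of the endothelial and fibroblast medians was -0.0208, below the lower quartile of the macrophage list (1.41). Sex of the animals or the slide itself cannot be told apart from the K-line effect, since 0 K-line arrays are on the slide of the controls.

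Zbtb16, Cdkn1a and Mt1, known to respond to glucocorticoids, were among the largest falls in N-line. Lower glucocorticoid signalling is a hypothesis: 10 further glucocorticoid-induced genes had a median of -0.24, 8 of them lower and 0 called, with a camera p of 0.00390 that became 0.0687 with an estimated correlation. Among these, Cebpb was at -0.45 and Arrdc2 at -0.45, and in K-line the same genes had a median of 0.05. Handling or time of death, which also move these genes, were not tested.

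The arrays were also split in every other way into 3 and 3. With 10 splits per comparison, no share under 0.05 can be reached. Every other split also puts arrays of both groups on each side. A real difference then widens the spread, so few probe calls in the other splits follow from the design. The list counts of other splits reached those of the real split, so they do not set it apart. For K-line against control the real split gave 4795 probes and 5 lists, and the highest other 1 probe and 6 lists, with 1 and 4 of the splits as large. For N-line against control the real split gave 183 probes and 2 lists, and the highest other 0 probes and 2 lists (1 and 3 splits as large). Between the lines the real split gave 4774 probes and 4 lists, and the highest other 1 probe and 6 lists (1 and 4 splits as large).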
